A study of Arabidopsis thaliana with 16 samples.

How the data were processed

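Transcript levels were measured in shoots of Arabidopsis thaliana seedlings (ecotype Landsberg erecta) on 16 single-colour Affymetrix ATH1 arrays, one array per sample. Per the labels, 12 arrays came from a line with a dexamethasone (DEX) inducible rga-delta17 transgene, called the rga line here, and 4 from a line with the same vector and no transgene, called the vector line. The rga line had 3 biological replicates in each of 4 groups (mock or DEX, 2 h or 4 h), and the vector line had 2 in each of 2 groups (mock or DEX, 4 h only). Seedlings were 8 days old, had been sprayed with 2 µM of the gibberellin GA4 16 h earlier, and received GA4 again (mock) or GA4 with 10 µM DEX.

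The deposited values are intensities on a linear scale, 1 per probe set, which the authors made with MAS5, per the submitters' processing notes. The version of MAS5, the scanner settings and the detection calls are not given in the sources used here. In the deposited file the mean signal after trimming 2% at each end was 500.05 on all 16 arrays, so each array had been scaled to 1 target. That scaling was kept. Array medians ran from 138 to 193, the lowest 2 being those of the vector line with DEX. For arrays, their number limits the precision: 3 per group in the rga line and 2 in the vector line.

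Of 22810 probe sets, 64 controls were left out of the tests. Values under the 10th percentile of all deposited values (a signal of 7.95) were set to it, log2 was taken, and the 25% of probe sets with the lowest mean log2 value over all arrays were left out, which left 17059. A fold against a group whose arrays all lay at that floor is given as "at least". The probe table names 1 gene for 13513 probe sets, several for 503 and none for 8730; symbols were updated through the gene identifiers of the RefSeq table (assembly TAIR10.1), and 13436 probe sets had a locus there. Unlisted probe sets are unnamed here, and probe sets with several genes were not named. Each probe set was tested by itself.

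All arrays entered 1 limma fit (R 4.3.3, limma 3.58.1) with 6 group means and 10 residual degrees of freedom; eBayes used a mean-variance trend, and calls were made at a Benjamini-Hochberg adjusted p below 0.05 over the probe sets tested. Errors of log2 changes are SEs of that fit. There were 8 comparisons: DEX against mock at 2 h, at 4 h and averaged over both times in the rga line, DEX against mock in the vector line, the difference of the 4 h DEX effects between the lines, the difference of the DEX effects between the times, 4 h against 2 h in mock, and the rga line against the vector line in mock. In the step on simulated data over 17059 probe sets, 50 were changed at each size and the rest left unchanged. Of changes of 0.5, 1, 2 and 3 on the log2 scale, the rga line's 4 h DEX comparison recovered 34%, 56%, 90% and 96%. The vector line comparison recovered 16%, 60%, 78% and 96% of them. These simulated comparisons gave 143 and 127 calls, where the real ones gave 880 and 8062. The adjusted p cutoff loosens as more probe sets change, so these rates do not measure recovery in the real comparisons.

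Genes were named by a rule set before the data were examined: the 10 largest rises and 10 largest falls of the 2 h and the 4 h DEX effects in the rga line, and 5 each way in the other comparisons, among called probe sets with 1 named gene whose groups did not overlap (the last condition not applied to differences of effects), and up to 4 members with the smallest p of each of 23 gene lists. For the difference between the lines, genes called at 2 h whose effect at 4 h went further in the rga line were added after their values had been seen. RGA, which the rule also asked for, is not reported here, and induction of the transgene by DEX was not analysed here. For a gene with several probe sets, a list used the brightest. Of the 23 lists, 7 had at least 3 tested members and were tested with camera (preset correlation 0.01, and an estimated correlation as the alternative): gibberellin perception and DELLA signalling, putative DELLA targets named by the study, the GASA family, expansins, XTH enzymes, auxin response and root markers. The tested members were 7 of 12, 6 of 12, 4 of 12, 7 of 15, 7 of 22, 3 of 17 and 3 of 12 of the lists in this order, so each test rests on part of its list. The other 16 lists had fewer than 3 tested members and were not tested as lists. The camera p-values are adjusted over the 7 lists within each comparison. Gene families by symbol stem, with at least 8 tested members (24 families), were added after the data had been seen.

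Alternatives were quantile normalization, centring on array medians, no floor, an offset of 43.3 in place of the floor, no filter on dim probe sets, leaving out the lowest 50%, eBayes without the trend, array weights, only the arrays compared, a replicate block in 2 forms, an added minimum of 1.5-fold, and each replicate left out in turn. A fit without the vector DEX arrays was added after the data had been seen. Replicates carry shared numbers in the labels; the check of whether they pair samples is given with the alternatives. Figures were drawn with matplotlib 3.10.9.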

Results

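The series asked which genes respond early to a DELLA protein, a nuclear repressor of gibberellin signalling. It used a plant line in which DEX switches on rga-delta17, a dominant form that gibberellin does not remove. Shoots of this line were profiled 2 h and 4 h after GA4 alone (mock) or GA4 plus DEX, with 3 biological replicates per group, and an empty vector line was profiled at 4 h with 2 per group. Replicate arrays of a group correlated at 0.963 to 0.977 over the 17059 probe sets tested. The 2 vector DEX arrays stood apart: they correlated with the other 14 arrays at 0.789 to 0.885, while those 14 correlated with each other at 0.916 to 0.975.

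**Figure D1:**
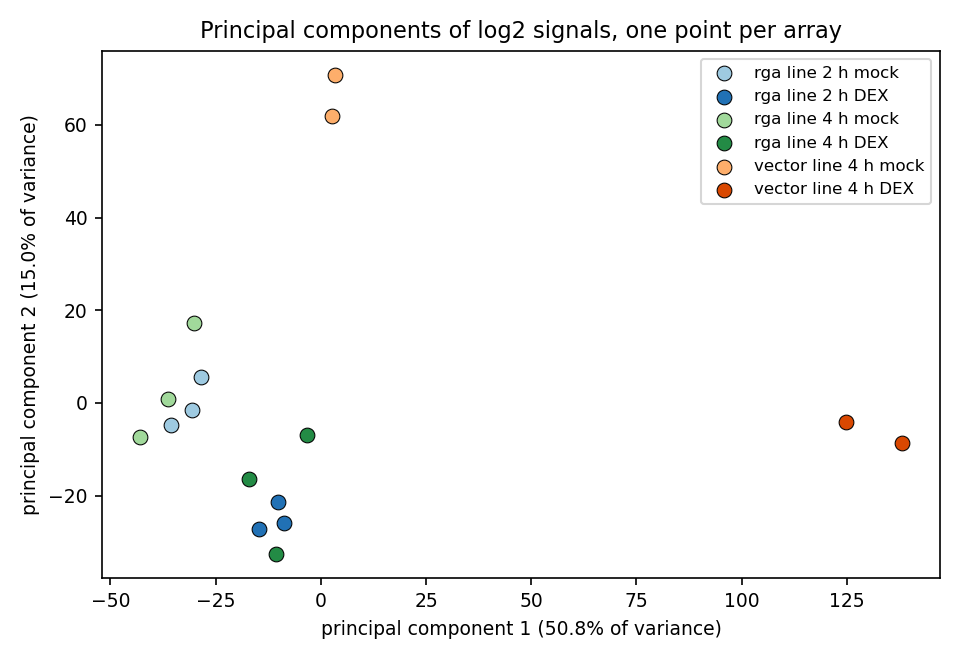
Principal components of the log2 signals of 17059 probe sets, 1 point per array, coloured by group; the axes give component 1 (50.8% of the variance) and component 2. The 2 vector DEX arrays lie at 125 and 138 on component 1, and every other array lies below 4.

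After 2 h of DEX in the rga line, MYBC1, a MYB-family transcription factor gene, rose most among named genes: its signal was 29.7 ± 39.7 in mock and 1907 ± 45.3 with DEX (mean ± SD, n = 3 each), a log2 change of 6.79 ± 0.54 (SE). AT4G22640 rose from 23.4 ± 24.0 to 639 ± 109, by 5.15 ± 0.56. AT1G64405, at the floor on all 3 mock arrays, rose to 270 ± 37.6, at least 33.7-fold. The metal transporter gene AT3G58060, of the cation efflux family, rose by 3.48 ± 0.60, AT4G25580 by 4.10 ± 0.35, and the GDSL lipase gene AT1G28590 by 3.34 ± 0.60. For MYBC1, AT4G22640, AT4G25580 and AT1G28590, 1 of 3 mock arrays lay at the floor, so these sizes depend on it. Among genes that fell, UGT74F1, which codes for a glucosyltransferase of salicylic acid, went from 120 ± 25.6 to 20.3 ± 12.4, and the pectin methylesterase inhibitor family gene AT5G62360 went from 1032 ± 242 to 423 ± 20.9, a log2 change of -1.27 ± 0.20.

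Of the 12 genes listed as putative DELLA targets that the study itself put forward, 6 were tested and the others were not analysed here. At 2 h, 5 of these 6 were higher, none was lower and the receptor gene GID1A was not called (0.28, adjusted p = 0.306), with a median log2 change of 1.17; all 6 were higher when adjusted over the list alone. IQD22, a calmodulin-binding protein gene, rose by 1.58 ± 0.16, the bHLH gene AT5G50915 by 1.55 ± 0.18, the gibberellin receptor gene GID1B from 328 ± 59.1 to 922 ± 83.7, and the bHLH gene AT2G31730 by 0.84 ± 0.16. XERICO, a RING finger gene linked to abscisic acid accumulation, rose by 0.70 ± 0.15. The 6 tested members ranked above other genes in camera (adjusted p = 2.58e-12; adjusted p = 0.000256 with an estimated correlation). The study chose this list on these samples, so its direction, its counts and this p are not independent evidence.

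Fewer members of the other tested lists were called at 2 h. In gibberellin perception and DELLA signalling, 2 of 7 members rose (3 when adjusted over the list alone): GID1B, shared with the list above, and SLY1, the F-box gene that targets DELLA proteins, by 0.50 ± 0.12. That list passed camera (adjusted p = 0.00131; adjusted p = 0.0153 with an estimated correlation), which is not independent evidence either as far as it rests on GID1B. Of 7 XTH genes, which remodel xyloglucan in cell walls, EXGT-A3 rose by 0.69 ± 0.10 and 6 were not called. Of 3 auxin response genes, GH3.3, which conjugates auxin to amino acids, fell by 0.82 on the log2 scale (SE 0.16), while IAA29 (1.66 ± 0.51, adjusted p = 0.0857) and WES1 (0.33 ± 0.16) were not called; adjusted over the list alone, 1 was higher and 1 lower. None of 7 expansins, 4 GASA genes or 3 root markers was called. Outside the tested lists, the dehydrin gene COR47 rose by 1.05 ± 0.14 and the clock gene GI by 0.72 ± 0.10.

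In all, 706 probe sets were called at 2 h, 515 higher and 191 lower. The fall of BZIP61, a bZIP transcription factor gene, by 2.87 on the log2 scale (SE 0.73) was lost without any of 4 of the 6 arrays, that of AT1G11700 without any of 5, and SLY1's rise without any of 4.

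At 4 h MYBC1 again rose most among named genes. It went from 7.66 ± 4.38 to 1474 ± 183 (n = 3 each), a log2 change of 7.30 ± 0.54 with 2 of 3 mock arrays at the floor, and AT4G22640 rose by 6.36 ± 0.56, AT1G64405 by 5.01 ± 0.34 and AT3G58060 by 4.09 ± 0.60. Genes among the 10 largest rises at 4 h but not at 2 h were AT3G10590 (3.75 ± 0.38), AT1G30700, a berberine bridge enzyme family gene (3.61 ± 0.50), the late embryogenesis abundant gene AT4G13230 (3.61 ± 0.52), the auxin response repressor gene IAA20 (3.51 ± 0.62), from 17.7 ± 13.6 to 177 ± 64.4, and the EF-hand gene AT3G01830 (3.42 ± 0.33). The floor was reached on 1 of 3 mock arrays for AT4G22640 and AT4G13230 and on 2 for AT1G64405. The largest called falls with a named gene were those of AT2G30680 (-1.71 ± 0.44), AT5G03390 (-1.59 ± 0.36), AT4G27657 (-1.45 ± 0.38), AT1G19960 (-1.45 ± 0.30) and AT2G05540 (-1.22 ± 0.21), while BZIP61 (-2.17, adjusted p = 0.113) was not called. Among falls of brighter genes, AT1G29660, a GDSL lipase gene, went from 1320 ± 91.1 to 586 ± 66.9 (-1.18 ± 0.14), the expansin-like gene EXLA1 from 484 ± 94.0 to 212 ± 24.1 (-1.18 ± 0.21) and GH3.3 from 906 ± 162 to 414 ± 74.1 (-1.13 ± 0.16).

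All 6 tested putative DELLA targets rose at 4 h, with a median of 1.09, also when adjusted over the list alone (not independent evidence, as at 2 h). AT5G50915 rose by 2.12 ± 0.18, GID1B by 1.91 ± 0.17, IQD22 by 1.30 ± 0.16 and GID1A, a receptor gene not called at 2 h, by 0.69 ± 0.12. Camera gave an adjusted p of 2.92e-14, and an adjusted p of 0.000132 with an estimated correlation, again not independent evidence. Of the 7 genes of gibberellin perception and DELLA signalling, 2 rose, both receptors GID1A and GID1B (3 when adjusted over the list alone; camera adjusted p = 0.000372, and adjusted p = 0.00894 with an estimated correlation). Both receptors are also on the list the study chose, and the other 5 genes changed by -0.08 to 0.34 without a call, so this test is not independent evidence. The expansin list shifted down in camera (adjusted p = 0.00901, median -0.73), a call lost with an estimated correlation (adjusted p = 0.0963); EXLA1 was its only called member of 7, and 2 were lower when adjusted over the list alone. XTH32 rose by 0.62 ± 0.09, and the other 6 XTH genes were not called (2 were higher when adjusted over the list alone). The list median (-0.39) and the camera direction (up, adjusted p = 0.871) differed in sign. COR47 rose by 1.22 ± 0.14 and GI by 0.63 ± 0.10, while no GASA gene or root marker was called (1 GASA gene was lower when adjusted over the list alone).

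At 4 h 880 probe sets were called, 615 higher and 265 lower. The count was 509 without DEX replicate 1, 580 without DEX replicate 3, and 568 when at least 1.5-fold was also required. The calls of AT4G27657, AT2G30680 and AT5G03390 were lost without any of 6, 4 and 2 of the 6 arrays, and without the filter on dim probe sets.

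The 2 h and 4 h comparisons use different arrays, so no shared array builds in their overlap. Both use the same spread estimate per probe set, which can raise the overlap of calls. Both called 354 probe sets higher, where independent lists of these lengths would share 18.6, and 63 lower, where 3.0 (2.97) would be shared. None was called in opposite directions. Averaged over both times, 1637 probe sets were called, 970 higher and 667 lower (635 with at least 1.5-fold). The 5 largest mean rises were MYBC1 (7.05), AT4G22640 (5.76), AT1G64405 (at least 5.04, its 2 h mock arrays all being at the floor), AT4G25580 (4.46) and AT3G58060 (3.79), and the largest mean fall with a named gene was BZIP61 (-2.52, adjusted p = 0.00339). Of the 7 gibberellin perception and DELLA signalling genes 4 were higher, GID1B (1.71 ± 0.12), GID1A (0.48 ± 0.09), SLY1 (0.33 ± 0.09) and SEC (0.32 ± 0.08), the calls of SLY1 and SEC each being lost without either of 2 arrays. All 6 tested putative DELLA targets were higher. The auxin genes went both ways, with IAA29 higher by 1.47 ± 0.36 (a call lost when only the arrays compared were used) and GH3.3 at -0.98 ± 0.11.

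In the difference of the 4 h and 2 h effects, limma gave 945 of 17059 probe sets at an unadjusted p below 0.05. A share of about 0.05 of unchanged probe sets passes that bound too. After adjustment 8 probe sets were called (5 higher, 3 lower), and 3 of them have 1 named gene. AT2G41730 rose by 0.65 at 2 h and 2.13 at 4 h, a difference of 1.48 (adjusted p = 0.0194). AT1G77770 changed by 1.24 and 0.25 (difference -0.99, adjusted p = 0.0194), and AT1G04800 by 0.23 and -0.85 (difference -1.08, adjusted p = 0.0251). No gene list was called; the GASA and expansin lists came nearest (both adjusted p = 0.0673, downward). The count was 0 without the filter on dim probe sets or without the trend, where limma gave 1367 and 949 probe sets at an unadjusted p below 0.05, and it ran from 3 to 9 when single arrays were left out. The calls of AT2G41730 and AT1G77770 were lost without any of 6 of the 12 arrays, and that of AT1G04800 without any of 9.

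Far more transcripts differed between DEX and mock in the empty vector line. AT4G22640 was at the floor on both vector mock arrays and reached 16327 ± 585 with DEX (n = 2), at least 2054-fold. AT4G13230 went from 21.9 ± 6.67 to 4133 ± 135, a log2 change of 7.59 ± 0.64, AT5G51950 changed by 7.42 ± 0.65, AT3G48950 by 7.17 ± 0.76 and AT1G28590 by 6.95 ± 0.73. The nitrate transporter family gene AT3G21670 went from 574 ± 50.4 to 17.9 ± 16.5 (-5.22 ± 0.39), AT5G44680 changed by -5.05 ± 0.43, AT5G62360 changed by -4.88 ± 0.25, and AT1G29660 from 1116 ± 227 to 43.1 ± 8.64 (-4.69 ± 0.17). The floor was reached on 1 of 2 mock arrays for AT3G48950 and AT1G28590 and on 1 of 2 DEX arrays for AT3G21670 and AT5G44680, so these sizes depend on it.

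Of 7 expansins, 5 were lower in the vector line with DEX and 1 higher: EXLA1 by -3.07 ± 0.25, EXLA2 by -3.10 ± 0.43 and EXPA15 by -2.05 ± 0.16, against 1.53 ± 0.14 for EXPA4, with EXPB3's call lost after quantile normalization. Camera did not call the list (adjusted p = 0.345). Of 7 XTH genes 3 were lower and 2 higher, with XTH33 at -3.66 ± 0.41 and XTH16 at -2.67 ± 0.20, and with EXGT-A3's rise (0.43 ± 0.13) lost without either of 2 arrays. GH3.3 went from 2036 ± 257 to 140 ± 13.6 (-3.86 ± 0.20), whereas WES1, another GH3 gene, rose by 2.35 ± 0.20 and IAA29 by 2.04 ± 0.62, a call lost without replicate 1 of either group. COR47 rose by 1.89 ± 0.18, GI by 1.13 ± 0.13 and the stress zinc finger gene STZ by 1.17 ± 0.21, while the cytokinin response regulator gene RR16 went to -2.00 ± 0.24. The putative DELLA targets went both ways: IQD22 rose by 2.19 ± 0.19 and GID1B by 1.18 ± 0.20, GID1A changed by -1.08 ± 0.15 and AT2G31730 by -1.35 ± 0.20. XERICO (-0.68 ± 0.18) and AT5G50915 (-0.72 ± 0.22) were also called lower, calls that were lost under both other scalings. Of the 4 GASA genes 3 were called lower, 1 of them under every scaling, and no root marker was called.

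In the vector line 8062 probe sets were called, 47.3% of those tested, with 3016 higher and 5046 lower. This split depended on the scaling: 37.4% of the calls were higher as deposited, 43.6% after quantile normalization and 58.1% after centring on array medians, and the median log2 change moved from -0.15 to -0.02 and 0.12. The 25S rRNA control probe set had a signal of 12808 ± 396 on the vector DEX arrays, 474 ± 73.5 on the vector mock arrays and 391 to 2046 on the rga arrays.

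The 4 h DEX effects of the lines were tested against each other; positive differences mean a higher DEX to mock ratio in the rga line. MYBC1, picked for this comparison after its values were seen, rose more in the rga line (7.30 against 3.53, difference 3.78 ± 0.86, adjusted p = 0.00244). Its levels with DEX were 1474 ± 183 in the rga line and 1144 ± 60.2 in the vector line, and its mock levels were 7.66 ± 4.38, with 2 of 3 arrays at the floor, and 99.5 ± 7.72. Several putative DELLA targets rose in the rga line at 4 h and were called lower in the vector line: the difference was 2.84 ± 0.28 for AT5G50915, 2.22 ± 0.26 for AT2G31730, 1.76 ± 0.20 for GID1A and 1.42 ± 0.23 for XERICO. Genes that rose much further in the vector line were AT2G23270 (-6.25 ± 0.83), AT3G48950 (-6.17 ± 0.99), AT3G62280 (-5.29 ± 0.41), the calmodulin-like gene CML37 (-4.93 ± 1.17) and LBD16 (-4.87 ± 0.41), a LOB-domain transcription factor gene. AT3G21670 (5.22 ± 0.50), AT1G70820 (4.39 ± 0.39) and AT4G09890 (4.33 ± 0.37) fell in the vector line and were not called in the rga line; AT3G21670 and AT3G48950 depend on the floor as above.

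**Figure D2:**
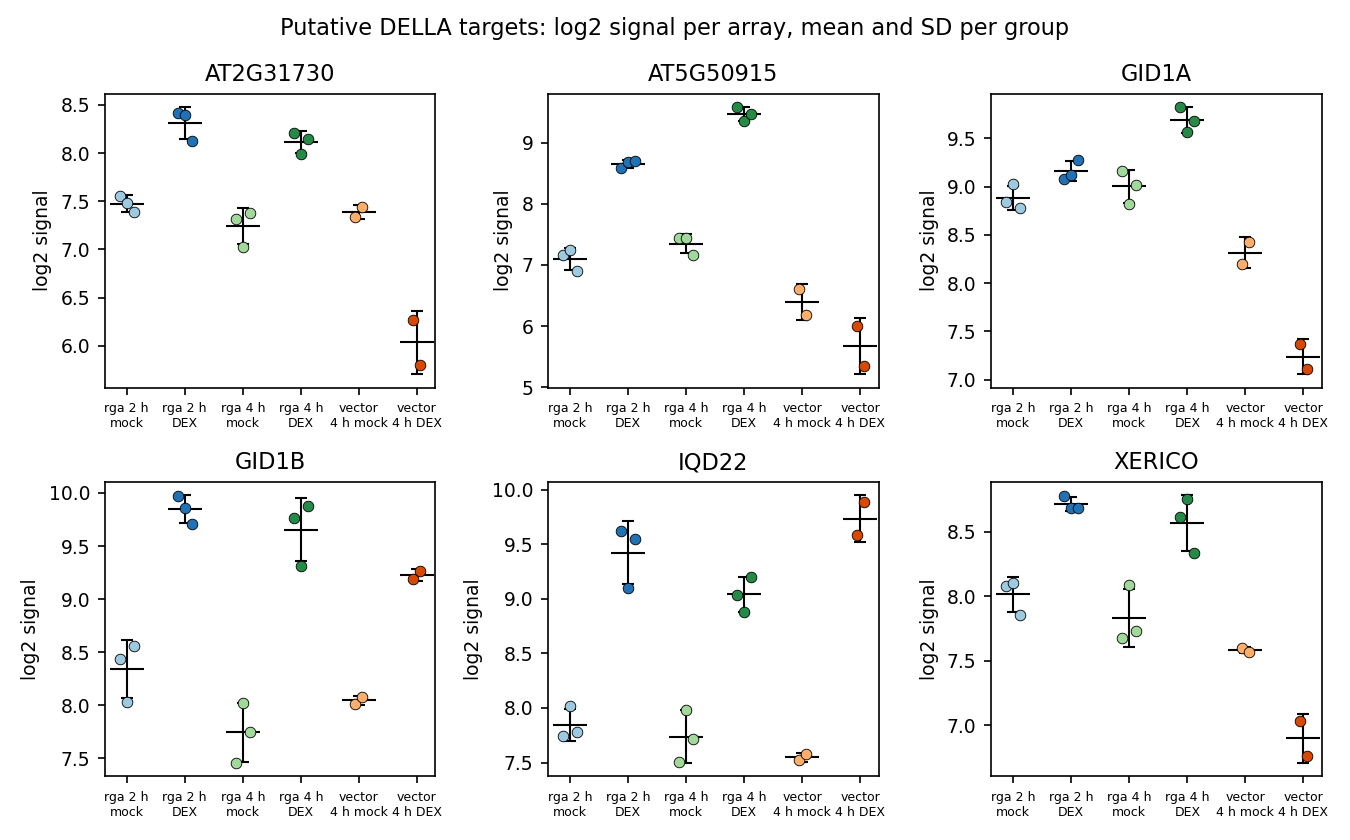
Log2 signal per array (y axis) of the 6 putative DELLA targets tested, by group (x axis); points are arrays, horizontal bars the group means and whiskers the SD (n = 3 in the rga line, 2 in the vector line). At 4 h with DEX all 6 were higher than mock in the rga line, whereas in the vector line IQD22 and GID1B were higher and GID1A and AT2G31730 lower.

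Of the 6 putative DELLA targets tested, 5 had a higher DEX effect in the rga line and IQD22 a lower one (-0.89 ± 0.25), also when adjusted over the list alone. Camera called the list (adjusted p = 0.0231), a call lost with an estimated correlation (adjusted p = 0.124). GID1B's difference (0.72 ± 0.26, adjusted p = 0.0447) was lost after median centring, without the filter or the trend, and without any of 8 of the 10 arrays. The study chose this list on these samples, so its direction, counts and p are not independent evidence. The expansins EXLA1 (1.90 ± 0.33), EXLA2 (2.27 ± 0.55) and EXPA15 (1.80 ± 0.20) had lower DEX effects in the vector line; of these only EXLA1 was called lower in the rga line too. Of 7 expansins 5 differed this way, also when adjusted over the list alone, and EXPA4 the other way (adjusted p = 8.78e-06). EXLA2, EXPA8 and EXPB3 lost their calls after quantile normalization, and camera did not call the list (adjusted p = 0.307). GH3.3 (2.73 ± 0.25), XTH33 (3.22 ± 0.53) and XTH16 (2.28 ± 0.26) also had lower effects in the vector line, GH3.3 alone of them being called lower in both, and WES1 differed by -2.37 ± 0.25.

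In all 5207 probe sets differed between the lines, 3412 higher and 1795 lower; the share of higher differences was 65.5% as deposited and 42.4% after median centring. Most responses of the rga line were shared with the vector line and smaller than there. Of the 706 probe sets called at 2 h in the rga line, on arrays not used in this comparison, 661 (93.6%) had the same sign in the vector line. Of the 706, 448 were called higher in both, where independent lists would share 91.1, 164 were called lower in both, where 56.5 would be shared, and 23 were called in opposite directions, where 186 would be. The spread estimate that both comparisons share can raise such overlaps of calls. Of the 515 higher at 2 h, the vector line's effect at 4 h was called further up for 327 and the rga line's for 43. Of the 191 lower at 2 h, the vector line's was called further down for 148 and the rga line's for 8.

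**Figure D3:**
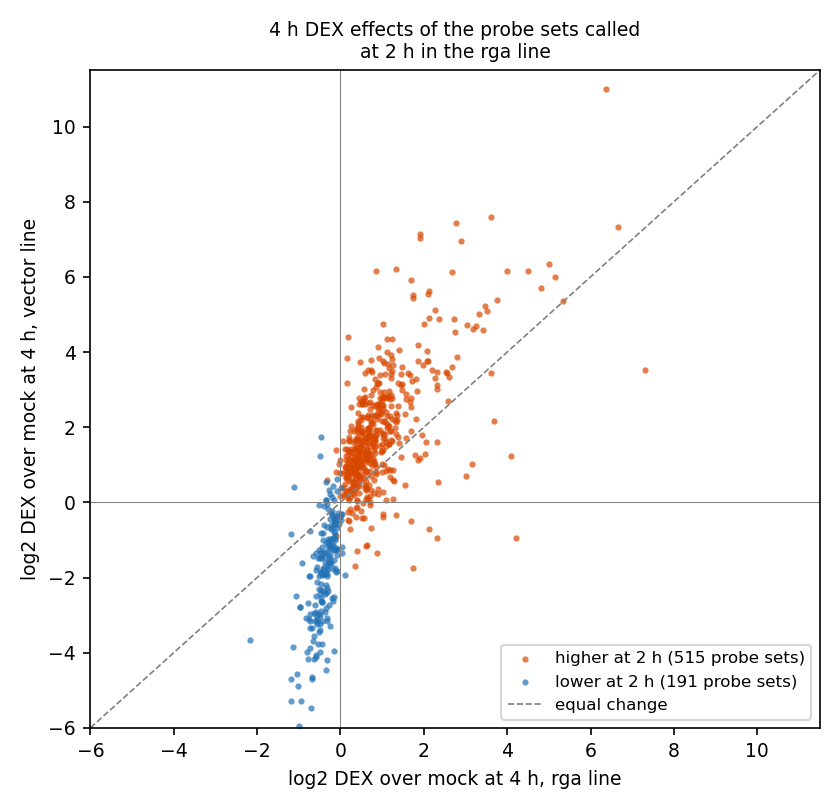
Log2 change of DEX over mock at 4 h in the rga line (x axis) and in the vector line (y axis) for the 706 probe sets called at 2 h in the rga line, 1 point each, coloured by their 2 h direction; the dashed line marks equal change. Of the points, 84.7% lie further from no change, in their 2 h direction, in the vector line than in the rga line.

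Without DEX, several genes differed between 4 h and 2 h in shoots of the rga line. CCR2, a cinnamoyl-CoA reductase gene of lignin synthesis, went from 142 ± 47.1 to 14.4 ± 10.1 (-3.45 ± 0.45), EXLA1 from 1374 ± 271 to 484 ± 94.0 (-1.51 ± 0.21) and AT2G44370 from 1259 ± 332 to 458 ± 174 (-1.51 ± 0.28). AT1G19960 rose by 1.68 ± 0.30 and EXGT-A3 by 0.55 ± 0.10, while GH3.3 changed by -0.81 ± 0.16 and XTH18 by -1.22 ± 0.29. No list was called by camera, and no gibberellin perception, GASA or root marker gene was called (1 gibberellin perception gene was lower when adjusted over the list alone). In all 263 probe sets were called, 68 higher and 195 lower. The count was 134, 137 and 161 without 2 h replicate 3, 4 h replicate 1 and 2 h replicate 1. It was 174 without the filter on dim probe sets, 98 without the trend, 117 from these 6 arrays alone and 173 with at least 1.5-fold. The replicate block within time, given with the alternatives, gave the lowest count and ended the calls of CCR2, AT1G19960, EXGT-A3, GH3.3 and XTH18. In that fit each time had its own block with replicate 1 as reference. It therefore set replicate 1 levels of the times against each other, not group means. Those losses do not show what pairing of replicates would do. XTH18's call was lost without any of 5 arrays. The calls of EXGT-A3 and GH3.3 were each lost without either of 2 arrays and without the trend, and AT2G44370's without 2 h replicate 3, the filter or the trend.

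In mock at 4 h many genes differed between the arrays of the lines. The beta-expansin gene EXPB2 was higher in the rga line, 111 ± 38.1 (n = 3) against 8.32 ± 1.71 (n = 2), a log2 difference of 3.62 ± 0.37 that depends on the floor, reached on 1 of 2 vector arrays. Lower in the rga line were the berberine bridge enzyme family genes AT1G26380 (39.3 ± 27.1 against 367 ± 45.4) and AT1G30700 (71.9 ± 52.2 against 618 ± 110), and MYBC1 (7.66 ± 4.38 against 99.5 ± 7.72, -3.42 ± 0.61), 2 of whose 3 rga arrays lay at the floor. The defence and stress genes WRKY53 (-1.85 ± 0.26) and STZ (-1.38 ± 0.19) were lower as well. Of 3 auxin genes GH3.3 (-1.18 ± 0.18) and WES1 (-0.70 ± 0.18) were lower. Camera called the list (adjusted p = 0.00532; adjusted p = 0.105 with an estimated correlation). GID1A (0.69 ± 0.14) and AT5G50915 (0.96 ± 0.20) were higher. Of the 3 root markers EXPA7 (1.58 ± 0.49) and EXPA18 (0.99 ± 0.32) were higher, calls lost after quantile normalization. WES1's call was lost without either vector mock array, GID1A's without vector mock replicate 1 and AT5G50915's without vector mock replicate 2.

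The lines' arrays also differed in controls added at hybridization, whose mean log2 signal was 10.84 on the vector arrays (10.75 to 10.96) and 10.23 on the rga arrays (10.08 to 10.61), so line and array batch cannot be told apart. Of 2994 called probe sets 1966 were higher and 1028 lower. The count fell to 1906 after quantile normalization, to 1888 without the lowest 50% of probe sets, and to 1691, 1424 and 1016 without rga mock replicate 1, vector mock replicate 1 and vector mock replicate 2. The share of higher calls was 65.7% as deposited, 53.7% after quantile normalization and 35.4% after median centring.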

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

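Tests chosen only after the result was seen are those of the scaling (both patterns it is weighed for), of a DEX response common to both lines, of degraded RNA, of the hybridization batch and of the dim end of the vector arrays. The comparisons of splits and the test of swapped line labels were set before. Groups of 2 or 3 arrays are too small for a test of single arrays that stand apart.

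The DEX effects of the lines at 4 h differed for 5207 probe sets by a test of the difference itself. The largest differences towards the rga line, on the log2 scale, were those of AT3G21670 (5.215), AT1G70820 (4.385), AT1G72230 (at least 4.382), AT4G09890 (4.331) and AT1G52770 (4.191). The largest towards the vector line were those of AT2G23270 (-6.247), AT3G48950 (-6.169), AT3G62280 (-5.289), CML37 (-4.931) and LBD16 (-4.873). Some of these sizes depend on the floor, reached on both vector DEX arrays for AT1G72230, on 1 for AT3G21670 and AT1G52770, and on 1 vector mock array for AT3G48950. Among gibberellin genes and putative DELLA targets, GID1A differed by 1.764, GID1B by 0.7246, AT5G50915 by 2.835, AT2G31730 by 2.223 and XERICO by 1.42. Among cell wall genes, EXPA15 differed by 1.799, EXPA4 by -1.497, EXLA1 by 1.898, EXLA2 by 2.27, XTH16 by 2.283 and XTH33 by 3.218. Hormone and stress genes were GH3.3 (2.73), WES1 (-2.366), COR47 (-0.6718), RR16 (1.639) and STZ (-1.423), and others were the clock gene GI (-0.4957), the cell cycle genes AT1G08180 (1.749) and SIM (0.8015), and the trichome regulator gene GIS (1.812). Quantile normalization ended the calls of EXLA2, COR47, GI, SIM and GIS, and median centring those of GID1B and SIM. Of the 10 arrays compared, GID1B's call was lost without any of 8, COR47's without any of 7, those of GI and SIM without any of 6 and GIS's without any of 4.

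Some genes called at 2 h went further in the rga line than in the vector line at 4 h, in their 2 h direction. They were picked after their values were seen: MYBC1 (3.777), AT3G58060 (2.859), the glucosyltransferase gene UGT73C1 (2.174), AT2G38970 (1.748) and AT1G14580 (1.08) upward, and AT1G67920 (-2.213), AT5G25940 (-0.7236), AT1G49500 (-0.5876) and AT1G31130 (-0.4516) downward. Quantile normalization ended the calls of AT3G58060 and AT1G31130, each of which was also lost without any of 6 of the 10 arrays, and AT1G49500's was lost without vector DEX replicate 2. AT3G58060 lay at the floor on both vector mock arrays and 1 vector DEX array. MYBC1 averaged 7.66 in the rga line, with 2 of 3 arrays at the floor, and 99.5 in the vector line in mock, and 1474 and 1144 with DEX.

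Many more probe sets differed between DEX and mock in the empty vector line (8062) than in the rga line at 4 h (880). Swapped line labels of the finished DEX arrays are argued against. Of 264 probe sets at least 4-fold apart between the lines in mock, 91.7% differed the same way in DEX. Of the 264, 218 were higher in the rga line, the direction that the dim end of the vector arrays also gives. Line and array batch cannot be told apart, so this test cannot decide on an exchange of plants or RNA before hybridization. The authors' scaling is argued against as the whole cause, since 4257 differences between the lines were left under quantile normalization. A DEX response common to both lines and larger in the vector line is consistent with 93.6% of the 2 h calls of the rga line having the same sign in the vector line, with a median change of 1.62 there and 0.59 in the rga line at 4 h. Why it would be larger there stays open, because line, array batch and any difference in the day of treatment cannot be told apart in this design.

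The 25S rRNA control probe set, a signal outside the comparisons, averaged 12808 on the vector DEX arrays, and the lower of these arrays was 6.12 times the highest other array. Degraded RNA in vector DEX beyond vector mock is argued against. Of 3 ratios of 3' to 5' control probe sets, 0 were higher on both vector DEX arrays than on both vector mock arrays. The actin ratio was 1.75 to 1.92 on the vector arrays and 1.48 to 1.71 on the rga arrays. The GAPDH and ubiquitin ratios overlapped between the lines. Whether RNA integrity differed between the lines was not tested. The hybridization batch of the vector line as a whole is argued against, since the higher vector mock array had 526, within the range of the rga arrays. A difference in how these samples were labelled or enriched for mRNA was not tested, and no biological explanation was tested.

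In mock at 4 h, more probe sets were higher (1966) than lower (1028) in the rga line against the vector line. The dim end of the vector arrays is consistent with this: the share of higher calls was 91.5% among the dimmest of 3 equal sets of probe sets and 41.3% among the brightest, 50.1 percentage points apart. The authors' scaling also fits, the share being 53.7% under quantile normalization. A difference between the lines themselves stays open, untested, for the genes that kept their calls.

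The DEX effects in the rga line differed between 2 h and 4 h for 8 probe sets, among them AT2G41730 (1.478), AT1G04800 (-1.076) and AT1G77770 (-0.9907). Of 100 splits of time within each treatment, 2 gave as many calls, the real one included, a share under the bound of 0.05. That share does not exclude chance for these 8 calls. Their count was 0 without the filter on dim probe sets, and another split gave far more. The highest other split gave 101 calls, over 12 times the real count, and the median of the others was 0. What gave so large a count from other labels was not tested, and that count limits what the 8 calls show.

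Counts of calls were also set against other splits of the same arrays. For the mean DEX effect of the rga line, 1 of 100 splits gave as many calls, the real one with 1637, and the highest other gave 210, so chance is excluded at a share of 0.05. With 10 splits each, a share under 0.05 is out of reach for the 2 h DEX effect (real 706, highest other 1), the 4 h DEX effect (real 880, highest other 16) and 4 h against 2 h in mock (real 263, highest other 1).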

How the results depend on the processing

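The fits without the vector DEX arrays were chosen only after the result was seen. Of 196 called values of named genes, 130 kept their call under every alternative, 66 lost it under at least 1, and none changed direction with a call. For CCR2 and AT1G19960 in the comparison of times in mock, the only loss was with the replicate block within time. That fit did not compare group means there, as given below. The gene list tests called 9 of 56, and 6 with an estimated correlation.

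The causes of the following changes in counts were not tested, except that an added fold limit leaves less to call by construction. The difference of the DEX effects between the times (8) gave 13 with an offset, 0 without the filter and 0 without the trend. The 4 h against 2 h comparison in mock (263) gave 174 without the filter, 98 without the trend and 117 from its own arrays. The comparison of the lines in mock (2994) gave 1906 after quantile normalization and 1888 without the lowest 50%. Requiring 1.5-fold left 568 of 880 at 4 h, 635 of 1637 for the mean and 173 of 263 in mock.

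Leaving out 1 array at a time gave 473 to 602 calls at 2 h, 509 to 813 at 4 h (509 without DEX replicate 1, 580 without DEX replicate 3), 1273 to 1636 for the mean, 6389 to 7094 in the vector line, 3953 to 5165 for the difference between the lines, and 3 to 9 for the difference between the times (3, 4 or 5 without any of 9 arrays). It gave 134 to 248 for time in mock (134 and 161 without 2 h replicates 3 and 1, 137 without 4 h replicate 1) and 1016 to 3130 for the lines in mock (1016 and 1424 without vector replicates 2 and 1, 1691 without rga replicate 1). A lone vector array is assumed to vary like the other groups.

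Replicate numbers showed little sign of pairing the samples. Deviations of same-numbered mock and DEX arrays correlated at 0.04, 0.06 and 0.02 at 2 h and at 0.11, -0.08 and 0.26 at 4 h. In every rga group, however, the 25S rRNA signal was lowest on replicate 3 (2 h mock 556, 2 h DEX 956, 4 h mock 392, 4 h DEX 391). Some pairing is therefore not excluded. With the replicate block the counts were 652, 838, 1652, 8009, 5128, 11, 237 and 1546, and with the block within time 647, 850, 1651, 8076, 5185, 4, 44 and 1746, in the order 2 h, 4 h, mean, vector line, lines, times, time in mock and lines in mock. The blocks were set per line, or per line and time, with replicate 1 as reference. A comparison across blocks therefore set replicate 1 levels, not group means, against each other. This applies to the lines in mock in both forms (1546 and 1746) and to time in mock with the block within time (44). These counts do not test the same comparisons as the main fit. The block within time ended the calls of CCR2, AT1G19960, EXGT-A3, GH3.3 and XTH18 for time in mock, with the same limit. Without the vector DEX arrays the counts were 707, 896, 1686, 8, 252 and 3040 for the 6 comparisons that do not use them. Signal over background limits the dim probe sets: 7.48% to 13.7% of values per array lay at the floor.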

Other observations

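The tests of gene families were all chosen only after the files were seen. Over the 8 comparisons 13 of 192 such tests were called by camera, and 0 with an estimated correlation, so none of the families below keeps its call.

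Of 37 genes of the UGT family, glycosyltransferases that act on small molecules, 7 were higher at 4 h of DEX in the rga line, none was lower and 30 were not called, with UGT73C1 at 1.69 ± 0.23 (SE). The camera adjusted p was 0.0177 over 24 families, and adjusted p = 0.203 with an estimated correlation. At 2 h 2 were higher and 1 lower, and in the vector line 9 were higher and 13 lower. For the mean of both times 7 were higher and 2 lower (camera adjusted p = 0.162). In the difference of the 4 h and 2 h effects, camera also called the family upward (adjusted p = 0.019). That call was lost with an estimated correlation (adjusted p = 0.21), and none of the 37 members was called there.

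In the vector line with DEX, where 5046 of 17059 probe sets were lower, 4 of the 24 families were called. Of 13 SWEET genes, which code for sugar transporters, 7 were lower, none was higher and 6 were not called, with SWEET11 at -3.60 and SWEET17 at -3.32 (adjusted p = 0.0211; adjusted p = 0.338 with an estimated correlation). Camera called the other 3 families upward. Of 9 genes with SEC symbols, a stem that mixes unrelated genes, 7 were higher (adjusted p = 0.00908, and 0.333 with an estimated correlation). Of 9 VPS genes 6 were higher and 1 lower (adjusted p = 0.0221, and 0.31 with an estimated correlation). Of 69 chloroplast-encoded genes 10 were higher, 1 lower and 58 not called (adjusted p = 0.00908, and 0.691 with an estimated correlation). That share of higher genes was not above the 3016 of 17059 probe sets called higher in all.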
